A study of Arabidopsis thaliana with 9 samples.

How the data were processed

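Messenger RNA of Arabidopsis thaliana inflorescences was sequenced in 9 libraries, 3 from each of 3 groups: untreated, cycloheximide for 2 h, and dexamethasone plus cycloheximide for 2 h. Plants of 1 genotype, 35S:AP1-GR ap1 cal, were used throughout, and samples were grouped by the labels alone. The kit that the labels name does not mark strand, while the design text calls the libraries strand-specific, so the strand handling is not settled. Values of antisense and overlapping loci are therefore uncertain.

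Per the submitters' processing notes, the authors used TopHat, Cufflinks and Cuffdiff with the TAIR10 build, and versions, parameters and the scaling between libraries were not given in the sources used here. The deposited FPKM, fragments scaled by locus length and library total, came with a confidence interval and a quantification status for each locus and library. Loci carry IDs of the kind that Cufflinks gives to assembled loci, and a locus can hold several genes, part of a gene, or sequence with no reference gene. The reference annotation at hand, of the TAIR10 sequence, was used for names and locus classes and gave 39.4% identical starts and 39.1% identical ends among 33944 pairs of gene and locus. A total of 520 annotated gene IDs of the table were absent from it. Coordinates are those of the deposited table, counted from 1.

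The table held 33871 loci, and 77 lacked the status OK in at least 1 library. Loci with status OK in every library and a mean FPKM of at least 1 over the 9 libraries were tested, 19569 in all: 17276 covering 1 gene, 809 covering several genes, 679 covering less than 50.0% of a gene, 221 antisense to a gene and 584 with no reference gene. FPKM is relative to the other transcripts of a library, so a few abundant loci can lower all others. A single short locus inside OPCL1 held 13.7%, 16.5% and 16.0% of the FPKM sum in the cycloheximide libraries and 22.7%, 22.5% and 22.1% in those with both compounds, and the highest locus in untreated libraries held 2.28%, 2.68% and 3.57%. FPKM of the shortest loci are inflated by their length, so these shares of the FPKM sum are not shares of reads. In cycloheximide replicate 1 the OPCL1 locus had 466080 FPKM, where 1 read at a locus of 101 bp stood for about 1240 FPKM. The shares therefore do not show that it lowered the other loci. A total of 859 tested loci were below 300 bp, and the fits were also run without them. Absolute depth is unknown. At the shortest loci 94% to 100% of values above 0 were whole multiples, within 0.02, of the value of 1 read, and the relative depth was 0.49, 1 and 0.627 in untreated replicates 1, 2 and 3, 0.614, 0.649 and 0.559 with cycloheximide and 0.711, 0.364 and 0.389 with both compounds. Pairs of replicates of a group correlated with r of 0.953 to 0.980 and no library was a duplicate.

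The tests were made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, moderated variances and Benjamini-Hochberg adjustment. All 9 libraries were fitted together, leaving 6 residual degrees of freedom, and adjusted p under 0.05 was a call. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Gene lists were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 21 lists with at least 5 tested members, and again with an estimated correlation and with fry. Of 422 list members 414 were matched to a gene by ID and symbol, 8 were left out for their name, 18 shared a locus with another gene, 3 had no locus and 356 were tested.

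The genes named were AP1 and CAL, then for each main comparison the 10 called single-gene loci with the largest rise and the 10 with the largest fall among those whose libraries separated by group. Up to 4 called members with the smallest p per list followed, or the 2 members with the smallest p where fewer were called. A set of 22 floral regulators was given whatever their result in the dexamethasone comparison. Genes without a symbol were left out with few exceptions, and larger changes at loci naming no single gene were passed over: 5 rises and 7 falls with dexamethasone, 13 and 5 with cycloheximide.

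Replicate numbers are shared between groups in the labels, and whether they pair the libraries was checked from the deviations from the group means. In the dexamethasone comparison same-numbered libraries correlated with r of 0.131 to 0.353, each of the 6 best with its own number, so the numbers were taken to pair them and a blocked fit was made as an alternative. The calls given are those of the fit without the block unless another fit is named. Correlations against untreated libraries were lower, and the numbers were not taken to pair those groups. The blocked fit still gave the untreated libraries the same replicate effects, except where a block on 6 libraries is named.

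The pipeline was tested on simulated data with 200 changed loci among 19569 for each comparison. In the dexamethasone comparison it called 27.9% of loci changed by a log2 fold of 0.5, 76.9% at 1 and 95.1% at 2, with 7 of 19354 unchanged loci called. For cycloheximide against untreated the shares were 40.7%, 73.3% and 93.0%, with 8 unchanged loci called. The simulated noise was independent between loci and had the same SD in every library, without pairing or changes shared within a library. The real median SD of log2 values was 0.107 in untreated, 0.149 in cycloheximide and 0.143 in dexamethasone + cycloheximide libraries. These shares may therefore not carry over to the real comparisons. Alternatives covered the pseudocount, the filter, the scaling, the variance model, the block, the groups in the fit and each library left out. Loci of at least 300 bp, single-gene loci, a variance for each group, the response score as a covariate and the block on 6 libraries were added after seeing the data.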

Results

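The data were 9 RNA-seq libraries from inflorescences of Arabidopsis thaliana plants of 1 genotype, 35S:AP1-GR in an ap1 cal background. In ap1 cal mutants the shoot apex proliferates as a mass of inflorescence-like meristems, and AP1-GR is the MADS-domain transcription factor APETALA1 fused to a hormone-binding domain of the glucocorticoid receptor, which dexamethasone releases into the nucleus. The plants were 5 weeks old and grown at 22 °C in long days. Inflorescences were left untreated, treated for 2 h with cycloheximide, an inhibitor of translation elongation that served as the mock treatment, or treated for 2 h with dexamethasone plus cycloheximide. Each group had 3 libraries, which the labels call biological replicates. Values were the deposited FPKM of 33871 loci on the TAIR10 build, of which 19569 were tested, and log2 fold changes below are on the scale of log2(FPKM + 1) with their SE, which understates the change of loci with low FPKM. The total read count per library was not given in the sources used here. The steps between FPKM values of the shortest loci gave a relative depth of 1 for untreated replicate 2, the deepest library, and of 0.364 for dexamethasone + cycloheximide replicate 2, the shallowest. The deposited confidence intervals had a median half-width of 62.6% to 63.6% of the FPKM per library, but in 434 to 500 tested loci per library the deposited upper bound lay below the FPKM itself, so these intervals were not used. Libraries of a group differed by a median absolute log2 difference of 0.0972 to 0.218 per pair, and the tests rest on this spread between the 3 libraries of each group.

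AP1 (AT1G69120, chromosome 1, 25982330 to 25986313), the gene carried by the transgene, was abundant in every library. Its FPKM was 1098, 1183 and 1380 in untreated replicates 1, 2 and 3, 1088, 1475 and 1536 with cycloheximide, and 989.9, 1576 and 1487 with dexamethasone + cycloheximide. Reads from the transgene and from the mutated AP1 locus are not separated in these values. The difference between the treated groups was -0.03 ± 0.23 (adjusted p = 0.955). CAL (AT1G26310, chromosome 1, 9100079 to 9103603), the related MADS-box gene mutated in this line, had 68.2 ± 6.08 FPKM (SD, n = 3) untreated, 47.4 ± 5.95 with cycloheximide and 38.3 ± 3.35 with both compounds. It fell with cycloheximide, by a log2 fold change of -0.52 ± 0.11 (adjusted p = 0.00481), while its difference between the treated groups, -0.29 ± 0.11, did not pass the test (adjusted p = 0.164) but did with the replicate number as a block (adjusted p = 0.0422).

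The comparison of dexamethasone + cycloheximide with cycloheximide asked which transcripts respond to activation of AP1-GR when translation is inhibited. All plants carried AP1-GR, so an effect of dexamethasone itself cannot be told apart from that activation. TFL1 (AT5G03840, chromosome 5, 1024551 to 1025852), which keeps the inflorescence meristem indeterminate, fell from 142 ± 24.0 FPKM (SD, n = 3) to 38.6 ± 6.04, a log2 fold change of -1.85 ± 0.15 (adjusted p = 0.00279). FD (AT4G35900, chromosome 4, 17004595 to 17006287), the bZIP partner of the flowering signal FT, fell from 237 ± 22.8 to 127 ± 6.8 FPKM (-0.89 ± 0.10, adjusted p = 0.00694), and its paralog FDP (AT2G17770, chromosome 2, 7722839 to 7724426) from 128 ± 14.0 to 61.8 ± 7.14 (-1.04 ± 0.11, adjusted p = 0.00704). LMI1 (AT5G03790, chromosome 5, 1004572 to 1006614), a homeodomain-leucine zipper gene that acts with LFY in floral fate, rose from 10.4 ± 1.01 to 18.5 ± 3.77 FPKM (0.76 ± 0.14, adjusted p = 0.0363). TFL1, FD and FDP were called in all 9 fits that left out 1 library, but LMI1 in only 2. With only the 6 libraries compared TFL1 was called (limma, adjusted p = 0.0277). FD, FDP and LMI1 were not called in that fit (limma, adjusted p = 0.0599, 0.0557 and 0.103). The untreated libraries had 149.6 ± 11.7 FPKM of TFL1, 234 ± 5.37 of FD, 148 ± 6.96 of FDP and 9.2 ± 1.06 of LMI1.

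In total 723 loci were called, 374 higher and 349 lower with dexamethasone, and 138 of the rises and 55 of the falls were at least a log2 fold change of 1. This balance of large changes was not stable. It was 15 and 26 without dexamethasone + cycloheximide replicate 3, and 370 and 65 without cycloheximide replicate 3. With a pseudocount of 0.1 it was 73 and 67. In all 374 rises and 349 falls, the 3 libraries of one group lay on one side of the 3 of the other. Over all tested loci this separation held for 25.4%, against 10% by chance. The largest falls among called loci naming a single gene were in AT3G56010 (-5.31 ± 0.77) and AT4G38330 (-2.77 ± 0.40), which have no symbol. The FPKM of AT3G56010 was 327, 3155 and 2225 in the untreated libraries, 729, 1805 and 1403 with cycloheximide and 28.4, 27.5 and 34.4 with both compounds, so its level before treatment also varied widely. LSH1 (AT5G28490, chromosome 5, 10453750 to 10455594), of the ALOG family of nuclear proteins, fell from 110.0 ± 9.64 to 24.3 ± 2.26 FPKM (-2.13 ± 0.14, adjusted p = 0.00129). KNATM (AT1G14760, chromosome 1, 5084352 to 5085213), a KNOX protein without a homeodomain, fell from 17.5 ± 4.08 to 5.19 ± 0.729 (-1.57 ± 0.18, adjusted p = 0.00952). ZPR2 (AT3G60890, chromosome 3, 22496926 to 22498002), a small leucine zipper protein that binds class III homeodomain-leucine zipper factors, and bZIP42 (AT3G30530, chromosome 3, 12139512 to 12140033) fell too, with log2 fold changes of -1.5 ± 0.24 and -1.48 ± 0.32. With the replicate number as a block bZIP42 was not called (limma, adjusted p = 0.0573).

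Among called loci naming a single gene, the largest rise with a symbol was in RALF1 (AT1G02900, chromosome 1, 653765 to 654343), a secreted signalling peptide, from 8.39 ± 3.94 to 47.3 ± 11.3 FPKM (2.42 ± 0.30, adjusted p = 0.0125). TPS02 (AT4G16730, chromosome 4, 9402898 to 9406026), a terpene synthase, rose by 2.17 ± 0.38 and ERF71 (AT2G47520, chromosome 2, 19502802 to 19503569), an ethylene response factor, by 2.13 ± 0.39. TPS02 and ERF71 (limma, adjusted p = 0.0317 and 0.0355) were called in 3 and 2 of the 9 fits that left out 1 library. RALF1, TPS02 and ERF71 had also risen with cycloheximide alone, by 1.95, 1.34 and 2.99. RL3 (AT4G36570, chromosome 4, 17254610 to 17255716), a MYB-like gene related to RADIALIS, went the other way between the treatments: its log2 fold change with cycloheximide alone was -0.87, and it rose with dexamethasone from 9.14 ± 1.97 to 41.3 ± 1.7 FPKM (2.08 ± 0.13, adjusted p = 0.00129). Genes without a symbol made up 6 of the 10 largest rises and 5 of the 10 largest falls.

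**Figure D1:**
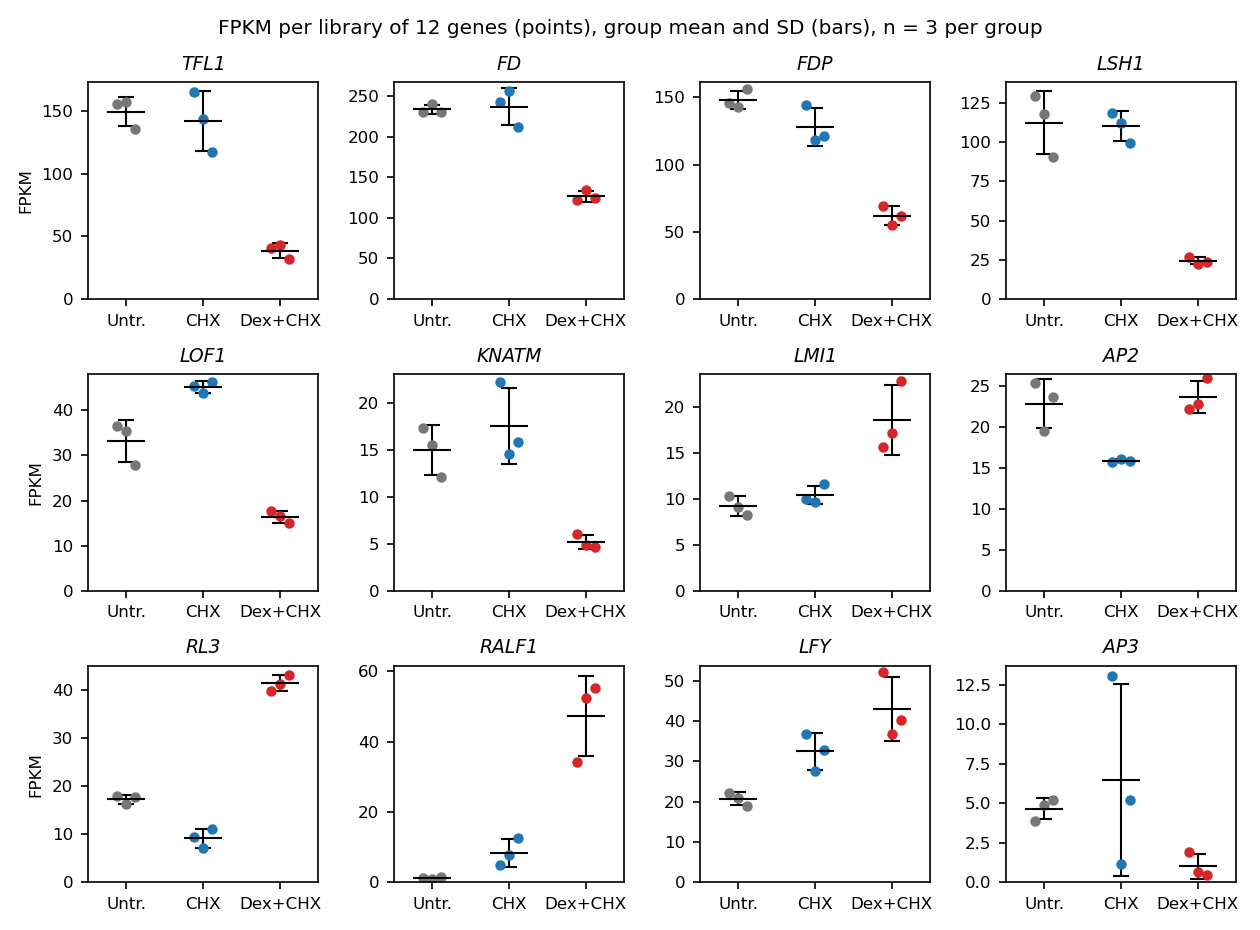
FPKM of 12 genes (y axes, linear from 0) in untreated libraries (Untr., grey), libraries with cycloheximide (CHX, blue) and libraries with dexamethasone + cycloheximide (Dex+CHX, red). Points are the 3 libraries of each group in the order of their replicate numbers, and black bars give the mean and SD. TFL1 lay between 31.8 and 43.4 FPKM in the red libraries and at 117 FPKM or more in the other 6, whereas AP3 varied from 1.16 to 13.0 FPKM within the cycloheximide group.

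Among the gene lists fixed before the data were examined, flowering time and inflorescence identity held more called members than any other. Of 26 tested members 8 fell and 18 were not called, and adjusted over the list alone 10 fell. Besides TFL1, FD and FDP, the transcription cofactor gene BOP1 fell by 0.74 on the log2 scale, from 17.9 ± 1.12 to 10.4 ± 1.24 FPKM, after a rise of 1.22 with cycloheximide alone. The SBP-box genes SPL9 and SPL15, which promote the floral transition, fell, at -0.72 and -0.49 (adjusted p = 0.0149 and 0.0377). The list as a whole lay lower, with a median log2 fold change of -0.26 (camera, adjusted p = 2.81e-06), and adjusted p = 0.297 with an estimated correlation.

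Of 16 tested floral meristem and organ identity genes 2 rose, LMI1 and AP2, none fell and 14 were not called, and adjusted over the list alone 2 rose and 1 fell (camera, adjusted p = 0.189). AP2, the floral homeotic gene that restricts AG, rose by 0.55 ± 0.10 (limma, adjusted p = 0.0362), after a log2 fold change of -0.49 with cycloheximide alone. The rise of AP2 was called in 3 of the 9 fits that left out 1 library. Of the 22 regulators fixed for this comparison 6 were called: TFL1, FD, FDP, SPL9, SPL15 and LMI1. LFY, a master regulator of floral fate, had 32.5 ± 4.64 FPKM with cycloheximide and 43.0 ± 7.98 with both compounds (0.39 ± 0.15, adjusted p = 0.161), and the flowering repressor SVP had 103 ± 7.58 and 73.0 ± 10.9 (-0.50 ± 0.11, adjusted p = 0.0546, but 0.029 with the replicate number as a block). BOP2 (-0.40 ± 0.10, adjusted p = 0.0654) and the petal and stamen identity gene PI (-0.67 ± 0.16, adjusted p = 0.0614) also missed the threshold. AP3, the partner of PI, had a difference of -1.57 ± 0.59, but its cycloheximide libraries gave 13.0, 1.16 and 5.19 FPKM (adjusted p = 0.163).

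The SEPALLATA genes, cofactors of the floral organ identity proteins, had log2 fold changes of -0.59 (SEP1), -0.42 (SEP2), -0.71 (SEP3) and -0.11 (SEP4), with adjusted p of 0.262, 0.202, 0.354 and 0.584. AG, which specifies stamens and carpels, had 1.43 ± 1.14 FPKM with cycloheximide and 0.222 ± 0.0832 with both compounds (adjusted p = 0.145). FUL (-0.03, adjusted p = 0.857), SOC1 (-0.16, 0.528) and AGL24 (-0.24, 0.248), MADS-box genes of the floral transition, were not called. The same held for the AP2-like repressors SNZ (-0.37, adjusted p = 0.374) and TOE1 (-0.00, 0.986) and for the repressor TEM1 (-0.17, 0.522).

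In the shoot meristem, organ boundary, organ polarity and growth regulator lists all calls over all loci were falls. Over the list alone the shoot meristem and boundary lists had rises too, and the lists were not tested together. In the shoot meristem list 1 of 19 members fell, the KNOX gene KNAT2, from 25.9 ± 2.91 to 15.5 ± 0.796 FPKM (-0.70 ± 0.09, adjusted p = 0.0125). Adjusted over the list alone 3 rose and 6 fell. The stem cell regulator WUS had 12.2 ± 0.124 FPKM with cycloheximide and 16.8 ± 2.13 with both compounds (adjusted p = 0.0614). The list lay lower by camera (adjusted p = 0.0213), with adjusted p = 0.622 when the correlation was estimated. Of 14 organ boundary and initiation genes 2 fell, and over the list alone 3 rose and 4 fell (camera, adjusted p = 0.239). LOF1 (AT1G26780, chromosome 1, 9270943 to 9272845), a MYB gene of organ boundaries, fell from 45.2 ± 1.26 to 16.4 ± 1.33 FPKM (-1.41 ± 0.11, adjusted p = 0.0027), and LSH4 (AT3G23290, chromosome 3, 8326825 to 8328132), a boundary gene related to LSH1, fell from 21.4 ± 1.55 to 9.33 ± 0.972 (-1.12 ± 0.11, adjusted p = 0.00593).

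Organ polarity genes included 2 falls among 14 tested, in PHV, a class III homeodomain-leucine zipper gene of the adaxial side (-0.60 ± 0.08, adjusted p = 0.0125), and in YAB3, a YABBY gene of the abaxial side (-0.59 ± 0.11, adjusted p = 0.0342). Over the list alone 8 fell. The list had a median of -0.33 and lay lower (camera, adjusted p = 3.79e-05), with adjusted p = 0.297 under an estimated correlation. Among 19 GRF and TCP growth regulators 2 fell and 17 were not called, with 3 falls over the list alone (camera, adjusted p = 0.092). They were GRF4, which promotes organ growth (-0.46, adjusted p = 0.0197), and the branching repressor TCP18 (-0.52, adjusted p = 0.0484).

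In the auxin list of 27, the efflux carrier genes PIN3 and PIN7 went opposite ways: PIN3 fell from 8.41 ± 1.09 to 3.99 ± 0.596 FPKM (-0.92 ± 0.12, adjusted p = 0.0125) and PIN7 rose from 12.1 ± 2.31 to 20.5 ± 2.22 (0.73 ± 0.14, adjusted p = 0.0377). Over the list alone 3 auxin genes rose and 1 fell (camera, adjusted p = 0.687). The DELLA repressors RGL2 and RGL3 were the 2 of 16 gibberellin genes called, at 0.61 ± 0.11 and 1.04 ± 0.22, with 3 rises and 1 fall over the list alone (camera, adjusted p = 0.97, with a median of -0.03 and a mean of 0.07). RGL3 was not called with the replicate number as a block (limma, adjusted p = 0.0506). The type-A response regulator ARR9 fell by 1.06 on the log2 scale, the 1 call among 21 cytokinin genes both over all loci and over the list alone (camera, adjusted p = 0.147). BR6OX2, an enzyme of brassinosteroid synthesis, rose by 0.93 ± 0.20, the 1 call of 9 genes by either adjustment. That list had a median of -0.04 and a mean of 0.11 (camera, lower, adjusted p = 0.97). The drought and abscisic acid marker RD29A fell from 20.3 ± 7.13 to 7.61 ± 1.37 FPKM (-1.26 ± 0.27), with 1 fall among 13 genes of its list, 3 over the list alone (camera, adjusted p = 0.114). With the block RD29A was not called (limma, adjusted p = 0.0556).

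A score of the cycloheximide response, chosen after seeing the data as the mean signed log2 change of 3741 loci that both treated groups shared relative to untreated, was 1.79, 2.11 and 2.35 in cycloheximide replicates 1, 2 and 3 and 2.44, 2.48 and 2.69 in the dexamethasone + cycloheximide libraries. The loci of the score include members of the stress, jasmonate, replication and ribosomal lists, and whether these or the mitotic list follow the score across libraries was not tested. Rapid stress response genes lay higher with dexamethasone, with a median of 0.39 over 26 genes (camera, adjusted p = 0.000161; adjusted p = 0.622 with an estimated correlation). Only the ethylene response factor ERF1 was called (1.11 ± 0.24, adjusted p = 0.0488), and 6 genes rose over the list alone. Jasmonate genes had a median of 0.55 over 16 genes (camera, adjusted p = 0.000158; adjusted p = 0.622 with an estimated correlation) and no called member by either adjustment. The synthesis gene OPR3 had 862 ± 205 and 1425 ± 259.7 FPKM (adjusted p = 0.104).

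DNA replication genes lay lower, with 2 falls among 13 and 4 over the list alone (camera, adjusted p = 6.71e-05; adjusted p = 0.589 with an estimated correlation). The called members were the D-type cyclin gene CYCD3;1, from 99.2 ± 11.3 to 68.8 ± 5.09 FPKM (-0.52 ± 0.10), and E2FA, a transcription factor of S-phase entry (-0.41 ± 0.09). E2FA was not called with the replicate number as a block (limma, adjusted p = 0.0514). Mitotic cell cycle genes had a median of -0.19 over 17 genes with no call by either adjustment (camera, adjusted p = 0.00127; adjusted p = 0.622 with an estimated correlation). Its member with the smallest p, CYCA1;1, had 26.4 ± 3.97 and 20.9 ± 1.1 FPKM. Cytosolic ribosomal protein genes had a median of -0.13 over 16 genes, again with none called (camera, adjusted p = 0.0467; adjusted p = 0.754 with an estimated correlation). The response score above differed between the treated groups in the direction in which these stress, jasmonate, replication, mitotic and ribosomal lists had moved with cycloheximide alone. With the score as a covariate the stress, jasmonate, mitotic and ribosomal lists turned direction, and the ribosomal list was then called higher (camera, adjusted p = 0.0151, against a range of 0.000544 to 0.478 over its alternatives). Of the 9 list calls only those of flowering time and organ polarity held in the same direction with the covariate. The score holds members of the stress, jasmonate, replication and ribosomal lists, so the covariate takes out part of their own shift. What happened to those calls therefore cannot show what moved these lists.

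Epidermis markers had a median of -0.30 over 6 genes, with 0 calls over all loci and 3 falls over the list alone (camera, adjusted p = 0.0127; adjusted p = 0.323 with an estimated correlation). CER1, a wax synthesis gene, had 55.0 ± 5.17 and 37.1 ± 6.22 FPKM (adjusted p = 0.065). Of the anther and pollen markers 2 were tested, too few for a list test: the anther receptor kinase gene EMS1 rose by 0.51 ± 0.11, and TPD1, which encodes its ligand, had -0.03 (adjusted p = 0.919). EMS1 was not called with the replicate number as a block (limma, adjusted p = 0.0556). No member was called among 15 photosynthetic tissue markers (camera, adjusted p = 0.239), 9 heat shock genes (0.0613), 17 circadian clock genes (0.672) or 25 splicing factors with isoforms sensitive to nonsense-mediated decay (0.631). Over the list alone 1 clock gene rose, BOA (0.48, adjusted p = 0.0566 over all loci), and none of the other 3 lists had a call. LHCB4.2 (0.42), HSP101 (0.20) and PTB2 (0.19) had the smallest p of theirs.

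**Figure D2:**
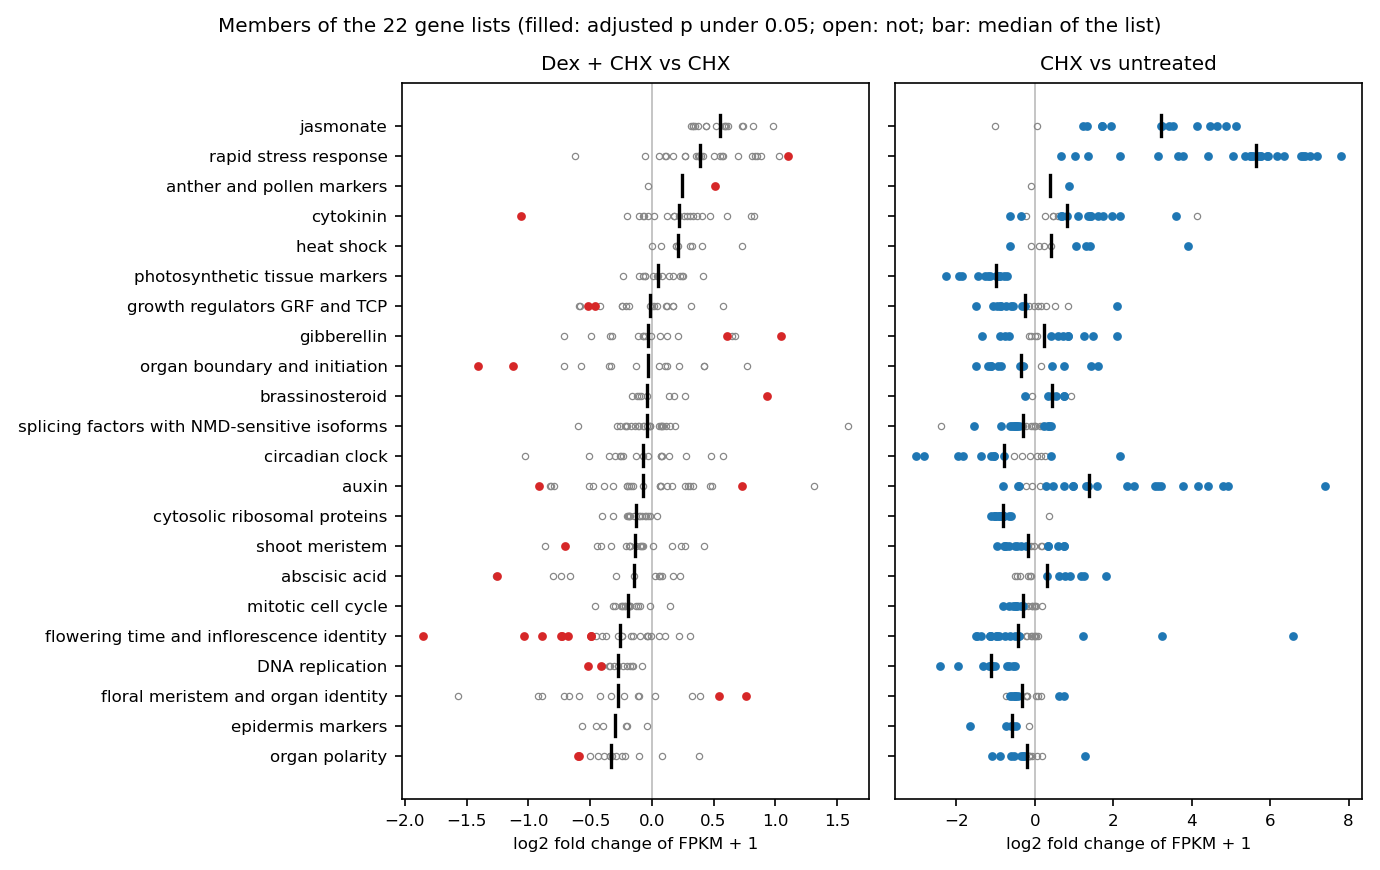
Log2 fold changes of FPKM + 1 (x axes) of the tested members of the 22 gene lists (y axis), for dexamethasone + cycloheximide against cycloheximide (left) and cycloheximide against untreated (right, wider scale). Filled points passed the test, open points did not, and black bars are list medians. The flowering time and inflorescence identity list has 8 filled points on the left, all below 0, and the rapid stress response list has 26 on the right, all above 0.

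The count of calls moved with the fit. It was 1102 (635 higher, 467 lower) with the replicate number as a block, 41 with only the 6 libraries compared, and, in fits added after seeing the data, 287 with a variance for each group and 6 (all lower) with the response score as a covariate. With the block CAL, SVP, BOA and CER1 were called (adjusted p = 0.0422, 0.029, 0.0442 and 0.044), and so was ABF3, a transcription factor gene of the abscisic acid list (adjusted p = 0.0487). E2FA, EMS1, RD29A, RGL3 and bZIP42 were not called with it (adjusted p = 0.0514, 0.0556, 0.0556, 0.0506 and 0.0573). Over all alternatives except the fold minimum the adjusted p ranged from 0.029 to 0.954 for the first 5 of these genes and from 0.0299 to 0.402 for the other 5. Without untreated replicates 1, 2 and 3 in turn it was 246, 157 and 391, without the cycloheximide replicates 125, 125 and 1248, and without the dexamethasone + cycloheximide replicates 315, 220 and 69. Of the 45 called genes named for this comparison 12 were called without each library in turn and 10 with only the 6 libraries compared. The block on the same 6 libraries, also added after seeing the data, called 1544 loci, 1024 higher and 520 lower, and 554 of them were among the 723. With it 5 of the 45 lost their call and 7 other named genes gained one. Other than with a minimum fold change, 1 of the 45, TFL1, was called in every alternative run for it, and 2 of the 45 were called with the covariate. RGL3, EMS1, TCP18 and bZIP42 lost their calls in each of the 9 fits that left out 1 library. AP2, ARR9, RGL2 and TPS02 kept their calls in 3 of these fits and LMI1 and ERF71 in 2. SPL15, YAB3, PIN7, CYCD3;1, BR6OX2, E2FA, ERF1 and RD29A kept theirs in 1. Camera called 9 lists, while 4 of the 10 splits of the 6 libraries, the real one included, gave at least 9 and another split gave 11.

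Cycloheximide against no treatment compared the mock treatment as a whole with its absence. The labels name no solution or handling for the untreated inflorescences. Effects of these and of the 2 h elapsed cannot be told apart from those of cycloheximide. Rapid stress response genes rose without exception, 26 of 26 over all loci and over the list alone. The zinc finger gene STZ, a stress-induced repressor, rose from 11.9 ± 0.398 FPKM (SD, n = 3) to 1902 ± 419 (7.18 ± 0.17, adjusted p = 1e-07), the ethylene response factor gene ERF2 from 4.19 ± 1.03 to 589 ± 35.4 (6.85 ± 0.15, adjusted p = 9.3e-08), and WRKY40, a WRKY factor of defence, from 11.2 ± 0.473 to 1463 ± 321 (6.89 ± 0.18, adjusted p = 1.4e-07). DNA replication genes fell, 13 of 13 by either adjustment, with the sliding clamp gene PCNA1 going from 62.8 ± 7.04 to 11.3 ± 3.31 FPKM (-2.4 ± 0.19, adjusted p = 2.26e-05). The camera adjusted p was 1.26e-16 for the stress list and 1.14e-06 for the replication list, and with an estimated correlation the adjusted p was 0.253 for both.

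In all 10712 loci were called, 5193 higher and 5519 lower, and 2468 of the rises but 841 of the falls were at least a log2 fold change of 1. The 3 libraries of one group lay on one side of the other 3 in 5133 of the rises and 5420 of the falls, and in 64.1% of all tested loci against 10% by chance. Quantile normalization moved the split to 3819 higher and 7999 lower (32.3% higher against 48.5%), and moved the median log2 fold change of all loci from -0.05 to -0.22, so small changes are relative to the scale used. Among called loci naming a single gene and separating the groups, the largest rise was in CRK41 (AT4G00970, chromosome 4, 418400 to 421835), a cysteine-rich receptor-like kinase gene, at 11.21 ± 0.80, with FPKM of 1.28, 1.77 and 1.89 untreated and 2109, 8305 and 13854 with cycloheximide. ZAT7 (AT3G46090, chromosome 3, 16926216 to 16926850), a zinc finger gene, rose by 8.24 ± 0.25 and CML37 (AT5G42380, chromosome 5, 16942576 to 16943366), a calmodulin-like gene, by 8.13 ± 0.18. Genes without a symbol made up 7 of the 10 largest rises and 3 of the 10 largest falls.

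By the same ranking the largest fall, in the thiol oxidase gene QSOX2 (AT2G01270, chromosome 2, 139331 to 142563), was -4.97 ± 1.66, but its FPKM was 728, 24.3 and 22.7 in the cycloheximide libraries and 22.3, 844 and 22.4 with both compounds, and its call was lost in 5 of the 9 fits that left out 1 library. Other falls were those of AGP21 (AT1G55330, chromosome 1, 20648465 to 20648891), an arabinogalactan protein gene, from 120.1 ± 8.85 to 10.5 ± 1.72 FPKM (-3.4 ± 0.20), and of TIP2 (AT3G26520, chromosome 3, 9722443 to 9723815), a tonoplast aquaporin gene, from 729 ± 83.6 to 82.8 ± 20.5 (-3.15 ± 0.19). TT4 (AT5G13930, chromosome 5, 4488688 to 4490264), the chalcone synthase gene of flavonoid synthesis, fell by 2.99 on the log2 scale, and LHB1B2 (AT2G34420, chromosome 2, 14522524 to 14523568), a light-harvesting protein gene, fell by 3.01.

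Most tested jasmonate, auxin and cytokinin genes rose. In the jasmonate list 14 of 16 rose by either adjustment, among them the synthesis genes AOS (4.14 ± 0.22), LOX3 (4.65 ± 0.27) and LOX4 (5.14 ± 0.28) and the transcription factor gene MYC2, from 117 ± 9.87 to 1295 ± 304 FPKM (camera, adjusted p = 8.19e-07; adjusted p = 0.374 with an estimated correlation). Auxin genes rose in 19 and fell in 3 of 27 cases, 20 and 3 over the list alone (camera, adjusted p = 2.02e-06; adjusted p = 0.253 with an estimated correlation). GH3.1 and GH3.3, which conjugate auxin, rose by 7.39 ± 0.34 and 4.92 ± 0.21, and the synthesis gene YUC1 from 2.74 ± 0.196 to 20.7 ± 1.14 FPKM. Cytokinin genes rose in 12 and fell in 2 of 21 cases by either adjustment (camera, adjusted p = 0.00202; adjusted p = 0.374 with an estimated correlation), among them the type-A response regulators ARR5 (3.6 ± 0.32) and ARR7 (1.96 ± 0.16).

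Of all tested loci 10712 of 19569 were called in this comparison, the background for the counts of the lists that camera did not call. Of 16 gibberellin genes 8 rose and 4 fell by either adjustment (camera, adjusted p = 0.211), with the catabolic gene GA2OX2 up by 1.25 ± 0.10 and GASA4, a gibberellin-induced gene, down from 992 ± 96.8 to 394 ± 52.9 FPKM. Abscisic acid genes rose in 7 of 13 cases by either adjustment (camera, adjusted p = 0.211), including the synthesis gene NCED3 (1.81 ± 0.28) and the phosphatase gene ABI1 (1.18 ± 0.08). The rise of HAI3 (0.63 ± 0.15) was not called after quantile normalization. Of 9 brassinosteroid genes 5 rose and 1 fell by either adjustment (camera, adjusted p = 0.0789), with the catabolic gene BAS1 at 0.74 ± 0.09. Heat shock genes rose in 4 and fell in 1 of 9 cases by either adjustment (camera, adjusted p = 0.0994): the repressor gene HSFB2A rose by 3.9 ± 0.16, while the chaperone gene HSP90.1 fell by 0.62 on the log2 scale.

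Developmental regulators changed in both directions. TEM1 and TEM2, repressors of flowering, rose by 3.24 ± 0.14 and 6.58 ± 0.15, whereas SPL15 fell by 1.14 on the log2 scale. Their list of flowering time and inflorescence identity had 3 rises and 14 falls among 26, 3 and 15 over the list alone (camera, lower, adjusted p = 0.020; adjusted p = 0.374 with an estimated correlation). LFY rose from 20.7 ± 1.61 to 32.5 ± 4.64 FPKM (0.62 ± 0.15, adjusted p = 0.00756) and the floral F-box gene UFO by 0.75 ± 0.13, while the carpel patterning gene ETT fell by 0.62. Floral meristem and organ identity had 2 rises and 6 falls among 16 by either adjustment (camera, adjusted p = 0.269). In the shoot meristem list WUS rose by 0.75 ± 0.10 and its regulator CLV1 by 0.59 ± 0.07, AIL7 fell by 0.97, and 5 rose and 9 fell of 19 by either adjustment (camera, adjusted p = 0.37).

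Organ initiation genes DRN and DRNL rose by 1.61 ± 0.11 and 1.44 ± 0.12, and the boundary gene CUC1 fell by 1.19 on the log2 scale, in a list with 4 rises and 8 falls among 14 by either adjustment (camera, adjusted p = 0.303). The abaxial gene FIL fell by 1.09 and KAN3 rose by 1.28, with 1 rise and 7 falls among 14 polarity genes by either adjustment (camera, adjusted p = 0.0884). Among 19 growth regulators 1 rose, GRF8 (2.1 ± 0.13), and 10 fell, including GRF7 (-1.49) and GRF1 (-1.06), with 1 and 11 over the list alone (camera, adjusted p = 0.0768). TPD1 rose by 0.87 ± 0.14, and EMS1 had -0.10 (adjusted p = 0.454). Splicing factors went both ways, 4 up and 9 down of 25, 4 and 8 over the list alone (camera, adjusted p = 0.267), with SCL33 at -0.63 and RS31A at 0.41.

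Markers of photosynthetic tissue fell, 13 of 15 over all loci and 15 over the list alone (camera, adjusted p = 4.02e-07; adjusted p = 0.193 with an estimated correlation). The light-harvesting genes LHCA1 and LHCB3 went from 238 ± 11.5 to 61.6 ± 2.34 and from 248 ± 9.02 to 51.0 ± 3.89 FPKM. Epidermis markers fell in 5 of 6 cases by either adjustment (camera, adjusted p = 0.020; adjusted p = 0.253 with an estimated correlation), including CER1, from 174 ± 18.5 to 55.0 ± 5.17 FPKM. Cytosolic ribosomal protein genes fell in 15 of 16 cases, and over the list alone 1 rose and 15 fell (camera, adjusted p = 3.34e-05; adjusted p = 0.374 with an estimated correlation). RPL5B went from 574 ± 10.3 to 331 ± 35.7 FPKM. Clock genes fell in 9 and rose in 2 of 17 cases by either adjustment (camera, adjusted p = 0.00745; adjusted p = 0.253 with an estimated correlation). Among them LNK1 (AT5G64170, chromosome 5, 25672466 to 25676746) fell by 3.03 on the log2 scale, GI (AT1G22770, chromosome 1, 8061799 to 8067716) fell by 2.81 and PRR5 fell by 1.36, and BOA rose by 2.17. Mitotic genes fell in 8 of 17 cases by either adjustment (camera, adjusted p = 0.0383; adjusted p = 0.635 with an estimated correlation), including the kinase gene AUR2 (-0.81 ± 0.10).

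Of the 11 lists called by camera here the epidermis, flowering time and mitotic lists were not called after quantile normalization, all 11 calls were lost with an estimated correlation, and 4 of the 10 splits of the 6 libraries gave at least 11 lists. A total of 102 of the 104 called genes named for this comparison were called in every alternative run for them other than a minimum fold change, the exceptions being HAI3 and QSOX2. With a log2 fold change of at least 1 required, 36 of the 104 were no longer called.

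Loci called in both comparisons mostly changed in the same direction: 290 rose in both, against 99.2 for independent lists, and 177 fell in both, against 98.4. Another 66 fell with dexamethasone and rose with cycloheximide, against 92.6, and 20 rose with dexamethasone and fell with cycloheximide, against 105. RL3 and AP2 were among the latter and BOP1 among the former. The cycloheximide libraries enter both comparisons with opposite sign, which by itself gives a negative relation. Across loci the log2 fold changes had a Pearson r of 0.397 and a covariance of 0.220. Unchanged groups simulated in the same layout, with noise independent between loci, gave -0.504 and -0.0376 (50 draws), a difference of 0.258 in covariance. The simulation lacks changes that many loci share within a library. The same sign was seen in 68.1% of loci, against 33.4% simulated. With 3 shared libraries they cannot be divided between the comparisons, and loci are not independent replicates. Of the dexamethasone calls, 64 of 374 rises (17.1%) and 106 of 349 falls (30.4%) had no call for cycloheximide, TFL1, FD and LSH1 among the falls.

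Dexamethasone + cycloheximide against no treatment combined both effects and was used for counts alone. It gave 12505 called loci, 6035 higher and 6470 lower, with 2977 and 1604 of them at least a log2 fold change of 1, and 70.0% of tested loci separated the groups against 10% by chance. Quantile normalization gave 4529 higher and 8874 lower (33.8% higher against 48.3%), with the median log2 fold change of all loci moved from -0.06 to -0.25.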

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

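The variance for each group, the response score as a covariate, the block on 6 libraries, loci of at least 300 bp and single-gene loci were tests chosen after seeing the data. For dexamethasone + cycloheximide against cycloheximide, 723 calls became 41 (14 higher, 27 lower, 39 shared with the 723) with only the 6 libraries compared, 193 with an absolute log2 fold of at least 1, 287 with a variance for each group, 6 (all lower, 3 shared) with the covariate, 1102 with the replicate block and 1544 with the replicate block on 6 libraries. Leaving out 1 library gave 69 (without dexamethasone + cycloheximide replicate 3) to 1248 (without cycloheximide replicate 3), and the other alternatives gave 494 to 946. With a fold minimum 3309 loci were called for cycloheximide against untreated and 4581 for dexamethasone + cycloheximide against untreated. No other alternative moved those 2 counts by over 1.5 times, and leaving out 1 library gave 8680 to 10905 and 10956 to 12676. The block gave 11573 and 13276. Same-numbered libraries correlated there with r of 0.0319 to 0.108 (4 of 6 best with their own number) and -0.115 to 0.0622 (3 of 6). With 3 libraries per group these values neither establish nor exclude a pairing. Camera with an estimated correlation called 0 lists in both main comparisons (3 in each at an unadjusted p under 0.05), against 9 and 11 with the preset one, and fry 3 and 17. With the covariate 5 lists reversed direction in the dexamethasone comparison, at adjusted p of 0.0151 (ribosomal), 0.925 (jasmonate), 0.157 (mitotic), 0.0969 (rapid stress) and 0.000594 (splicing factors). The block changed no list call, and of the genes named only 10 calls in the dexamethasone comparison, 5 gained and 5 lost. Leaving out 1 library gave 7 to 11 lists for dexamethasone and 10 to 11 for cycloheximide. The cause was not tested, except as weighed under the other observations. None of the called named genes reversed in any alternative run. Relative depth, as read from the steps at the shortest loci, was lowest in dexamethasone + cycloheximide replicates 2 and 3 (0.364 and 0.389). What this did to low loci was not tested.

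In 1 of the 10 splits of the 6 libraries, the real one, as many loci were called: 723 against at most 2 in another split for dexamethasone, 10712 against 2 for cycloheximide and 12505 against 1 for both compounds against untreated. Lists were as many in 4 of 10 splits in each main comparison, 9 against a highest other of 11, and 11 against 13. With 10 splits a share under 0.05 cannot be reached. Every other split holds libraries of both groups on each side. A real difference between the groups then widens its spread, so few calls there are no separate evidence. Of the dexamethasone splits, 3 others part all 3 pairs as the real one does and called 0 loci.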

Other observations

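The tests of scaling, of continuation and of the shared libraries were chosen after the result was seen, and so were the genes of this paragraph and the next, apart from ZPR2. ZPR1 (AT2G45450, chromosome 2, 18733275 to 18734127), a paralog of ZPR2, fell from 22.0 ± 3.46 to 8.58 ± 2.81 FPKM (SD, n = 3), a log2 fold change of -1.3 ± 0.27 (limma, adjusted p = 0.0429), after -1.08 with cycloheximide alone. TAS3 (AT3G17185, chromosome 3, 5861491 to 5862437), whose transcript is the source of small RNAs against auxin response factor genes, fell from 14.2 ± 2.59 to 5.71 ± 0.515 FPKM (-1.16 ± 0.13, adjusted p = 0.00708), against -0.07 with cycloheximide. The sugar transporter gene SWEET10 (AT5G50790, chromosome 5, 20656253 to 20658001) fell from 4.56 ± 0.43 to 1.27 ± 0.82 FPKM (-1.36 ± 0.26, adjusted p = 0.0366).

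On chromosome 5, AT5G40348 (16136559 to 16141361, plus strand) had 0.236 ± 0.176 FPKM untreated, 146 ± 83.2 with cycloheximide and 544 ± 287 with both compounds, and rose with cycloheximide by 6.76 ± 0.48 (limma, adjusted p = 1.21e-05). MYB24 (AT5G40350, 16138524 to 16141134, minus strand), a MYB gene of stamen development, overlaps it and rose from 0.385 ± 0.396 to 39.8 ± 7.13 FPKM (4.9 ± 0.26, adjusted p = 2.91e-06). A short locus inside AT5G40348 (16136724 to 16137011) had 217, 0 and 0 FPKM in untreated replicates 1, 2 and 3, and the neighbouring gene AT5G40340 had 36.5 to 43.5 FPKM in the untreated libraries. With the strand handling unsettled, reads of the overlap cannot be assigned to either gene. Among loci of any kind, 65 of 221 antisense loci rose and 26 fell with cycloheximide, and 159 of 584 loci with no reference gene rose and 62 fell, against 4662 and 5111 of 17276 gene loci.

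Loci that rose with dexamethasone could reflect a cycloheximide response further advanced in those libraries, whose score was higher in all 3 of them. With the score as a covariate 61.8% of their median log2 fold was left (0.81 to 0.5, SE 0.145 to 0.177), and 52.8% without cycloheximide replicate 3. This share cannot decide whether that was the whole cause or a part, since calling favours loci with a small spread. The count of 6 calls with the covariate, all of them falls, was also known when the bound for this share was set. As many loci taken by the largest rise kept 34.0%, a check made after the result was seen. Scaling as the whole cause is argued against by the 97.2% left after quantile normalization. Continuation of the change from untreated remains open. It was measured from untreated to the mean of both treated groups, which holds part of the dexamethasone change itself. By this measure 78.6% of these loci had changed the same way by at least as much. That share lay between bounds set with the values in view, and activation of AP1-GR is open and untested.

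Loci that fell with dexamethasone kept 86.0% of their median log2 fold with the covariate (-0.62 to -0.53, SE 0.106 to 0.149), and 78.9% without cycloheximide replicate 3. This share alone cannot decide on a further advanced response as the whole cause, since calling favours loci with a small spread. Its bound was also set with the count of 6 calls known. After quantile normalization 105.8% was left, which argues against scaling as the whole cause. As many loci taken by the largest fall kept 94.1% with the covariate, a check made after the result was seen. From untreated to the mean of both treated groups 49.0% of the loci that fell had changed the same way by at least as much. The bound for this share was also set with the values in view. The measure again holds part of the dexamethasone change, which raises that share. Chance values that widen the fold of called loci can lower it. Continuation as the whole cause therefore stays open. With the covariate 6 falls were called, 3 of them also called without it. It lowered the median fold, raised its SE and took 1 degree of freedom, and which of these ended the other calls was not tested. A part in the change stays open for scaling as well, and an effect of AP1-GR is a candidate explanation left untested.

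The drop from 723 calls to 41 with only the 6 libraries compared may come from a larger spread among the treated libraries. The median SD of log2 values was 0.107 in untreated, 0.149 in cycloheximide and 0.143 in dexamethasone + cycloheximide libraries, and with a variance for each group 287 loci were called. With the replicate block on the same 6 libraries, which leaves fewer degrees of freedom still, 1544 loci were called, 554 of them among the 723. Differences between the numbered pairs, which the fit with 41 calls leaves in its spread, thus stay open as part of the drop. The covariance of the log2 fold changes of both main comparisons across loci, 0.220, lay outside the -0.0532 to -0.0295 simulated for the shared cycloheximide libraries with no effect. The simulated noise was independent between loci, so this cannot exclude chance changes that many loci share within the cycloheximide libraries.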
